A study of Mus musculus with 6 samples.

How the data were processed

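The series holds bulk RNA-seq of long-term hematopoietic stem cells (LT-HSCs) from old male C57/Bl6 mice, 22 to 24 months of age. Per the labels, the cells were sorted as lineage-negative, Sca1-positive, cKit-positive, CD48-negative and CD150-positive. From each of 3 mice, the 10% of LT-HSCs with the most surface CD61 (CD61High) and the 10% with the least (CD61Low) were collected, 5000 cells each. Per the labels' protocols, cDNA was made from 4 ng of total RNA with the SMART-Seq v4 kit and libraries from 1 ng of cDNA with the Nextera XT kit, neither of which marks the strand of the transcript. The titles name 1 mouse for each library, while the protocol speaks of pools of LT-HSCs. The 3 numbers are taken here as 3 animals, so that p-values of tests of single genes measure the spread between them.

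The deposited values are counts of reads per gene, not normalized. Per the submitters' processing notes, STAR 2.7, MultiQC and edgeR were used; the genome build and annotation are not given in the sources used here. The authors deposited 1 STAR gene count table per library and a table for the whole series. Each library table lists 55450 genes, and all 55450 versioned identifiers are those of GENCODE mouse release M21 on GRCm38, which supplied symbols, coordinates, biotypes and exon overlaps. The series table holds the 17500 genes with a summed count of at least 31, and 0 of its values differed from the library tables. The unstranded counts were used, because the share of stranded counts on the first strand was 49.9% to 50.0% in the 6 libraries. Lines that name no gene stayed out of library sizes and tests: unmapped reads were 4.36% to 10.9% of a library, multimapping reads 10.0% to 15.6%, reads outside genes 2.88% to 4.21% and ambiguous reads 3.55% to 4.37%. Without strand, reads of overlapping or antisense genes cannot be told apart, and reads shared by near-identical genes are left out by the counting.

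Total counts on genes ranged from 21354130 to 26398090 per library, and 21365 to 23884 genes had a count. A count of 0 in a library allows up to 3 counts, or 0.114 to 0.140 CPM, and this floor too covers counting error only. Intervals on shares of counts are Wilson intervals at the 95% level and cover counting error only, since the libraries carry no molecular identifiers. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom over the 15 pairs was 44.8.

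Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test with robust dispersion, TMM normalization, filterByExpr by group, two-sided, Benjamini-Hochberg adjustment over the 15610 genes kept). A gene was called at an adjusted p under 0.05. The design was fixed before the data were examined and had no block, because no source states that mouse was a covariate; the fit with the mouse number as a block was also set out then. The libraries that share a number come from the same animal per the titles. Deviations from the group means were correlated between libraries. The correlation was 0.236, 0.806 and 0.761 between the 2 libraries of mice 1, 2 and 3, against -0.823 to 0.374 for libraries of different mice. The value of mouse 1 lies below the 0.374 of CD61High of mouse 1 with CD61Low of mouse 3. The pairing therefore rests on the titles, and gene and list calls are given with the block as well as without it. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Values in CPM, counts scaled to a common library total, are TMM-adjusted, and log2 CPM values carry a prior count of 2. The difference between the 2 libraries of a mouse is given as CD61High minus CD61Low throughout.

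Gene lists were written from general knowledge before the data were examined, and 753 of their 754 symbols matched the annotation. The 29 lists were tested with camera in limma 3.58.1 on the edgeR fit (preset correlation between genes 0.01, two-sided, Benjamini-Hochberg adjustment over the lists). Camera compares a list with the other genes and, at this preset, takes genes as nearly independent. Its p-values therefore do not measure the spread between mice. The estimated correlation and fry, which tests whether a list's genes move one way on balance or, in its mixed form, in either direction, were run beside it. With an estimated correlation, camera's test has only the residual degrees of freedom. These were 4 without the block, 2 with it and 1 with it and without mouse 2. A list can hardly pass at so few, so a high p there does not argue against a list. For each list, calls are given over all genes and adjusted over the list alone. The genes named are Itgb3; the 12 genes per direction with the largest fold change among those called, with the same sign in 3 mice, a mean of at least 5 CPM and a symbol that is not a predicted model; all members of the gate marker list; and up to 4 members per list with the smallest adjusted p. Since no gene passed the unblocked test, the 5 genes per direction with the smallest p that met the other conditions were also named, and the rule for called genes was applied to the blocked fit. Genes outside this rule are marked as chosen after their values were seen.

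The steps were tested on simulated data: counts were drawn from the blocked fit, with its mouse differences kept, the CD61 effect set to 0 and known changes put in, 96 genes per fold size among 15118 genes tested. For CD61High against CD61Low without a block, 0% of the 2-fold and 0% of the 4-fold changes were recovered. With the mouse as a block, 41.7% of the 2-fold and 81.2% of the 4-fold changes were recovered, and 10.6% of the genes called had not been changed. Without mouse 2 and with the block, 38.5% and 84.4% were recovered, and 19.2% of the genes called had not been changed, so the share of false calls in the simulation exceeded the 0.05 that the adjusted p allows. A simulated list of 25 genes that was moved had a camera p of 7.3e-12 in this simulation without the block, and a list of 25 genes that was not moved 0.283. The simulated genes were drawn independently of one another, so these values do not show how camera behaves when genes are correlated.

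Alternatives covered the block, DESeq2 1.42.0, limma voom, the scaling, the low-count filter, the thresholds, protein-coding genes only, each library and each mouse left out, and for lists the correlation, the test and shared members. Fits that left out a single library had no block. Its mouse then stood in 1 gate only, so that differences between mice entered the gate difference. Fits with a neutrophil marker score as covariate, blocked fits with other scalings, fry with the block and list tests without mouse 2 were added after the data were seen. The centred score was -0.67 in CD61High and 1.17 in CD61Low of mouse 1, 3.06 and 3.98 in mouse 2 and -5.29 and -2.26 in mouse 3. It was thus lower in CD61High in each mouse. With the block, a fit with this score extrapolates the gate difference to an equal score that no mouse had.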

Results

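CD61 is integrin beta 3, encoded by Itgb3, which reaches the cell surface paired with integrin alpha IIb (CD41) or alpha V. The 6 libraries were 3 CD61High and 3 CD61Low samples of sorted LT-HSCs, 1 of each from 3 old mice. Total counts on genes were 21354130, 24799800 and 25019004 in the CD61High libraries of mice 1, 2 and 3, and 25588836, 26398090 and 24210825 in the CD61Low libraries. The single comparison of the design asks which transcripts differ between LT-HSCs with high and with low surface CD61 in old animals.

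Itgb3 mRNA (ENSMUSG00000020689.4, GRCm38 chromosome 11, 104608000 to 104670476) was not called as different between the gates. It stood at 191 ± 45.4 CPM (SD, n = 3) in CD61High and 253 ± 110 CPM in CD61Low. The log2 difference was -0.51 in mouse 1, 0.12 in mouse 2 and -0.57 in mouse 3. The log2 fold change was -0.41 (SE 0.39), and edgeR's quasi-likelihood test gave an adjusted p of 0.926. With the mouse as a block it was -0.32 (SE 0.17, adjusted p = 0.334), and with a neutrophil marker score added to the block 0.28. That score was chosen after seeing the data and was lower in CD61High in each mouse, so the value is an extrapolation. Without mouse 2 the block gave -0.56 (SE 0.11, adjusted p = 0.0522), and leaving out single libraries or mice moved Itgb3 between -0.72 (without CD61Low of mouse 2) and -0.20 (without CD61Low of mouse 3). Itga2b, which encodes alpha IIb (ENSMUSG00000034664.13, chromosome 11, 102453297 to 102470122), rose in CD61High by log2 2.42 (SE 0.17, adjusted p = 0.0308) with the mouse as a block; without it the estimate was 2.35 (SE 0.40) at an adjusted p of 0.652. Its level was 525 ± 137 CPM (SD, n = 3) against 103 ± 50.02 CPM, and its log2 difference was 2.64, 2.56 and 2.06 in mice 1, 2 and 3. Itgav, which encodes alpha V, had 36.3 ± 4.56 CPM in CD61High and 56.0 ± 17.9 CPM in CD61Low. Its log2 fold change in edgeR without the block was -0.63 (SE 0.27) at an adjusted p of 0.752. Over all 6 libraries it was not called with the block either. Without mouse 2 and with the block, Itgav was at -0.97 with an adjusted p of 0.0317.

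Gp5 and Gp9, subunits of the platelet receptor for von Willebrand factor, rose by log2 1.499 (SE 0.16) and 1.42 (SE 0.16) with the mouse as a block, both at an adjusted p of 0.0436. Cd34, a surface marker that rises as stem cells become progenitors, rose by 1.17 (SE 0.14, adjusted p = 0.0470). Procr, which encodes the endothelial protein C receptor, fell by 1.25 (SE 0.14, adjusted p = 0.0436) and Ly6a, which encodes Sca1, fell by 1.34 (SE 0.16, adjusted p = 0.0446). Each of the 5 genes had the same sign of the difference in 3 of 3 mice. In edgeR over all 6 libraries these calls exist with the mouse as a block and not without it, where the adjusted p of Gp5, Gp9, Cd34 and Ly6a was 0.652 and that of Procr 0.752. Without the block, DESeq2 called Gp5, Gp9, Cd34 and Ly6a, and edgeR without mouse 2 called Gp9, Cd34 and Procr.

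Without a block, edgeR called 0 of 15610 genes, with 1023 genes (6.55%) at an unadjusted p under 0.05 and a lowest adjusted p of 0.652. Without a block, DESeq2 called 133 genes and limma voom 0, with 1139 genes at an unadjusted p under 0.05. Once mouse 2 was left out, edgeR without a block called 133 genes, 70 higher and 63 lower (3305 at an unadjusted p under 0.05). With the mouse as a block, edgeR called 40 genes, 15 higher and 25 lower in CD61High, with 3242 genes (20.8%) at an unadjusted p under 0.05. DESeq2 with the block called 1524 genes and limma voom 489. Of the 40 genes, 39 had the same sign of the difference in all 3 mice, and the exception, Igkv6-15, an immunoglobulin gene chosen after its values were seen, had 0 counts in both libraries of mouse 3. The number rests on the libraries and the scaling: the block called 0 genes without mouse 1 (1540 at an unadjusted p under 0.05), 742 without mouse 2 and 7 without mouse 3. It called 88 genes with relative log expression factors, 8 with upper-quartile factors and 0 with library sizes alone (2988 at an unadjusted p under 0.05). All of the 40 genes that were tested kept their sign under each of these 6 settings, and 37 of the 39 tested without mouse 2 were called there in the same direction. These fits reuse the libraries that gave the 40 calls, and 39 of the genes had the same sign in all 3 mice. Kept signs therefore do not support the calls. Without the block, DESeq2 called 21 of the 40 in the same direction, and edgeR without mouse 2 called 22 of 39. With a neutrophil marker score added to the block, a term chosen after seeing the data, edgeR called 70 genes, and 6 of the 40 were called there in the same direction.

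**Figure D1:**
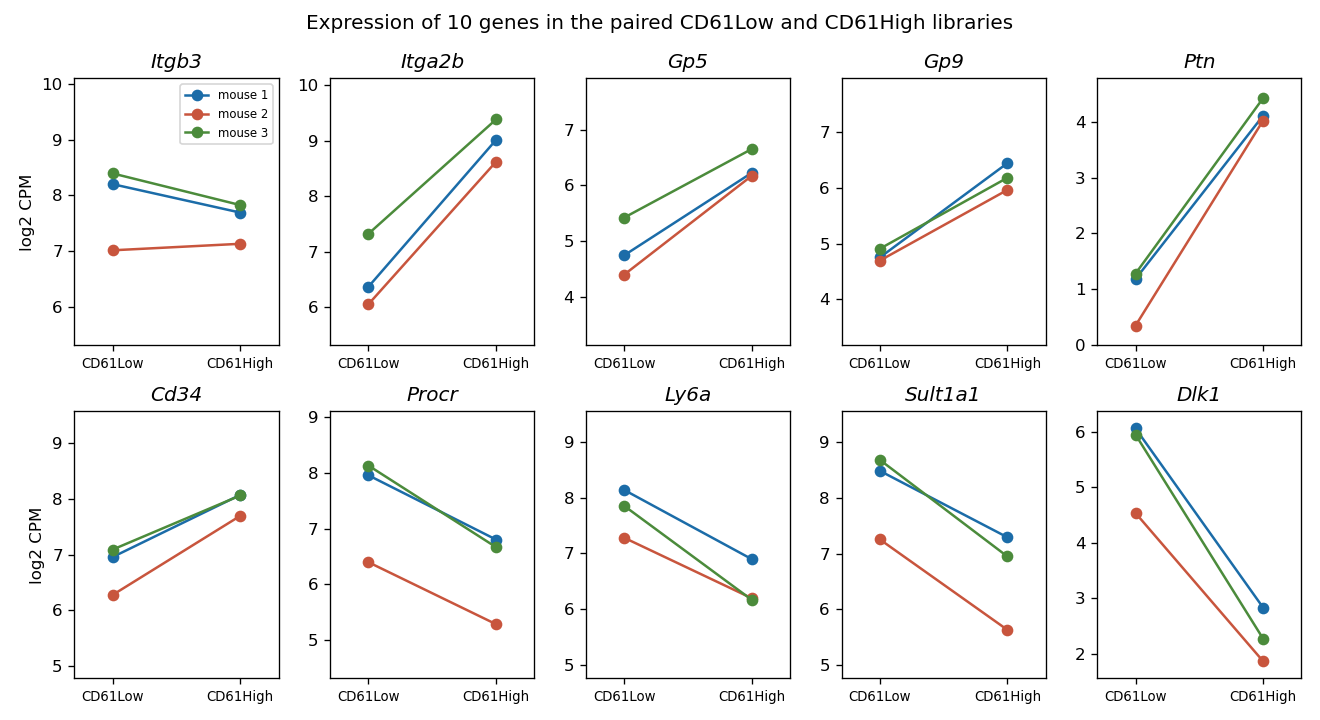
Log2 CPM of 10 genes in CD61Low and CD61High libraries, with a line joining the 2 libraries of each mouse; every panel spans the same number of log2 units. Itga2b, Gp5, Gp9, Ptn and Cd34 are higher and Procr, Ly6a, Sult1a1 and Dlk1 lower in CD61High in 3 of 3 mice, while Itgb3 is lower in 2 of 3.

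Among the 15 genes higher in CD61High with the block, Mc5r, a melanocortin receptor, rose by log2 3.41 (SE 0.30), Ptn, the heparin-binding cytokine pleiotrophin, by 3.29 (SE 0.27) and Fgf3, a fibroblast growth factor, by 3.28 (SE 0.30), from 2.07, 1.91 and 2.24 CPM in CD61Low to 21.2, 18.4 and 19.95 CPM in CD61High. Slc22a3, an organic cation transporter, rose by 2.66 (SE 0.26) to 83.6 ± 21.3 CPM (SD, n = 3), and Zdhhc2, a palmitoyltransferase, by 2.64 (SE 0.23) to 18.1 ± 5.26 CPM. Exoc3l4, H1fx, Arxes2, Slfn9 and Gdf3 rose by 1.43 to 2.26. H1fx and Exoc3l4 share 19.5% and 15.7% of their exon sequence with overlapping genes. The last of the 15 is Mlf1 (log2 3.41, SE 0.40), which was chosen after its values were seen. Psat1, an enzyme of serine synthesis, was higher in 3 of 3 mice and stood just outside the blocked call, with a log2 fold change of 1.07 (SE 0.15) and an adjusted p of 0.0512.

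Of the 25 genes lower in CD61High with the block, Dlk1, an imprinted Notch-family ligand, fell by log2 3.22 (SE 0.24), from 50.4 ± 23.7 CPM to 5.13 ± 1.77 CPM (SD, n = 3). Myh14, Bmp4, Cyp26b1, Plk2 and Alcam fell by 2.71, 1.81, 1.75, 1.67 and 1.59. Cyp26b1 degrades retinoic acid, and Alcam is an adhesion molecule of the immunoglobulin family. Fos, an immediate-early transcription factor, fell by 1.53 (SE 0.17), from 785 ± 319 CPM to 294 ± 186 CPM. Sult1a1, a sulfotransferase, and Plcl1 fell by 1.52 and 1.37, and Ldhd fell by 1.52 but shares 42.1% of its exon sequence with Znrf1. Iglc2, an immunoglobulin light chain constant region, and Tspo2, an erythroid gene, fell by 2.10 and 1.48. In CD61Low of mice 1, 2 and 3, Iglc2 had 8.46, 93.9 and 0.112 CPM and Tspo2 9.70, 113 and 2.23 CPM, and neither was called with the block once mouse 2 was left out (adjusted p = 0.0891 and 0.0665). Rin2, Rasa4, Ppp1r3b and Ccl4, which with Dlk1 had the smallest unadjusted p without the block among genes lower in CD61High with a mean of at least 5 CPM, had blocked log2 fold changes of -1.08, -1.38, -0.83 and -1.67 and adjusted p of 0.0512, 0.0512, 0.0648 and 0.0529.

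Transcripts of mature marrow cells, which the sort was set to exclude, differed between libraries. The first principal component of the 500 most variable genes held 90.6% of their variance and placed the libraries from CD61Low and CD61High of mouse 2 (80.8 and 60.6) through CD61Low and CD61High of mouse 1 (22.8 and -27.4) to those of mouse 3 (-54.2 and -82.7). The 20 neutrophil markers, such as Ngp and S100a8, took 7.78% (95% interval 7.77 to 7.79) of counts in CD61High and 12.5% (12.5 to 12.5) in CD61Low of mouse 2. In mouse 1 they took 0.596% (0.593 to 0.599) and 2.31% (2.30 to 2.31), and in mouse 3 they took 0.0442% (0.0433 to 0.0450) and 0.223% (0.221 to 0.225). B lineage, monocyte and T and NK cell markers were likewise a larger share in CD61Low in 3 of 3 mice, and erythroid genes in 2 of 3. Cd48, against which the cells were sorted, had 6.04 and 31.7 CPM of total counts in CD61High and CD61Low of mouse 1, 55.4 and 99.4 in mouse 2 and 1.16 and 1.86 in mouse 3.

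**Figure D2:**
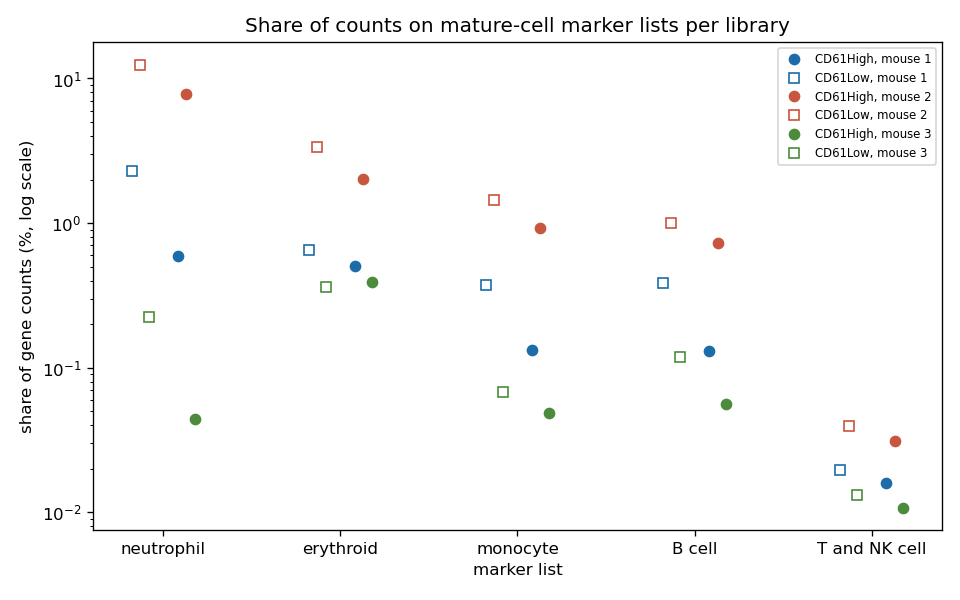
Share of gene counts on 5 lists of mature-cell markers in each of the 6 libraries, on a log axis; filled circles are CD61High, open squares CD61Low, and colours stand for mice. The neutrophil share spans 0.0442% to 12.5% and is higher in CD61Low in each mouse.

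The list of surface markers used to gate LT-HSCs was written from general knowledge. Per the labels, Ly6a, Kit, Cd48 and Slamf1 encode markers of this sort, while the markers encoded by Cd34, Flt3 and Procr are not named in it. Of the 7 genes, 1 rose (Cd34) and 2 fell (Procr and Ly6a) with the block. When adjusted over the list alone, 1 rose and 3 fell with the block. In edgeR without the block, Kit had a log2 fold change of 0.01 (SE 0.48), Slamf1, which encodes CD150, 0.18 (SE 0.54), Flt3 0.45 (SE 0.37) and Cd48 -1.28 (SE 1.77), with adjusted p of 0.996, 0.954, 0.895 and 0.940. Cd48 was lower in CD61High in each mouse, at 6.04 against 31.7, 55.4 against 99.4 and 1.16 against 1.86 CPM of total counts. Leaving out single libraries or mice moved Slamf1 between -0.20 and 0.53, Kit between -0.37 and 0.44 and Cd48 between -4.02 and 0.51, and Kit was below 0 with relative log expression or upper-quartile factors. As a list the markers did not pass camera (adjusted p = 0.789; median 0.01, mean -0.30), nor with the block (adjusted p = 0.242; median 0.17).

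Camera called 17 of the 29 gene lists, 5 toward CD61High and 12 away from it, and 21 with the mouse as a block. With an estimated correlation camera called 0, at a lowest adjusted p of 0.514, or 0.339 with the block. That test had 4 residual degrees of freedom, or 2 with the block. Hardly any list could pass at so few, so these 0 calls say little. Fry called 0 lists without or with the block. Its mixed form called 2 without the block and 19 with it, at a lowest adjusted p of 0.00332, and the 10 not called were the replication, G2/M, TGF-beta, oxidative phosphorylation, ribosomal, mitochondrial, B lineage, neutrophil, monocyte and endothelial lists. Leaving out CD61Low of mouse 2 left 10 called lists and leaving out CD61High of mouse 3 left 11.

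DNA replication and G1/S genes rose as a list in CD61High, with a median log2 fold change of 0.75 over 30 members and an adjusted p of 1.5e-12, which became adjusted p = 0.682 with an estimated correlation; with the block the median was 1.06. The median difference was 1.25 in mouse 1, -0.01 in mouse 2 and 1.86 in mouse 3, and 15 of 30 members were higher in all 3 mice. The median was 1.67 without CD61Low of mouse 2 and 0.44 without CD61Low of mouse 3. None of the 30 members passed over all genes, with or without the block, and 11 rose with the block when adjusted over the list alone. Without mouse 2, the block gave 22 members that rose over all genes. Pola1, a subunit of DNA polymerase alpha, had 118 ± 22.9 CPM (SD, n = 3) in CD61High and 51.2 ± 12.7 in CD61Low, and Chaf1b, a chromatin assembly factor, 185 ± 28.5 and 114 ± 6.86. The G2/M and mitosis list also rose (median 0.45, adjusted p = 8.8e-06; adjusted p = 0.729 with an estimated correlation), and with the block its median was 1.33 (adjusted p = 2.0e-09; adjusted p = 0.554 with an estimated correlation). Its median differences were 1.12, -0.28 and 3.20 in mice 1, 2 and 3. Of its 30 members, edgeR over all 6 libraries called 0 with or without the block, also when adjusted over the list alone. Without mouse 2, the block gave 1 member that rose over all genes and 4 that were higher when adjusted over the list alone. The list had an adjusted p of 0.158 without CD61Low of mouse 3. Leaving out single libraries moved its median between -0.05 (without CD61Low of mouse 3) and 2.26 (without CD61Low of mouse 2). Its members Ttk and Bub1b, both spindle checkpoint kinases, had log2 fold changes of 1.10 (SE 0.67) and 1.01 (SE 0.81). In mouse 2, neutrophil markers took 7.78% and 12.5% of counts. With the neutrophil score and the block together, the medians turned to -0.75 for the replication list and -1.85 for the G2/M list, in a fit that leaves 1 residual degree of freedom. The score was lower in CD61High in each mouse, so these medians are extrapolated to an equal score that no mouse had.

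Nuclear genes of oxidative phosphorylation rose as a list by a median of 0.13 (adjusted p = 0.00787; adjusted p = 0.729 with an estimated correlation). No member was called over the 6 libraries with or without the block, 18 were higher with the block without mouse 2 when adjusted over the list alone, and the median differences were 0.40, -0.21 and 0.36 in mice 1, 2 and 3. Ndufa9 and Uqcrc1 had log2 fold changes of 0.35 (SE 0.19) and 0.35 (SE 0.24). The call ended without CD61Low of mouse 1, CD61High of mouse 2 or CD61Low of mouse 3, with adjusted p of 0.384, 0.142 and 0.653. The median was 0.46 without CD61Low of mouse 2 and turned to -0.28 with the neutrophil score and the block together. Neutrophil markers were a smaller share in CD61High in each mouse, as 0.0442% against 0.223% in mouse 3.

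The platelet-biased HSC and megakaryocyte list passed in the direction of CD61High (adjusted p = 0.00525; adjusted p = 0.514 with an estimated correlation), although its median was -0.03, or 0.04 with the block, and its mean 0.32. Of its members, Itga2b, Gp5 and Gp9 rose with the block, 9 of 29 rose with it when adjusted over the list alone, and 3 of 29 were lower in all 3 mice. Platelet-abundant transcripts also rose as a list (median 0.10, mean 0.39, adjusted p = 0.00111; adjusted p = 0.514 with an estimated correlation), with the same 3 genes called with the block and 7 of 19 higher and 1 lower over the list alone. The median differences were 0.14, 0.30 and -0.02 for the first list and 0.07, 0.38 and -0.07 for the second in mice 1, 2 and 3. Platelet-abundant transcripts took 0.472% of counts in CD61High and 0.531% in CD61Low of mouse 1, 0.631% and 0.753% in mouse 2 and 0.472% and 0.434% in mouse 3. Leaving out single libraries or mouse 2 moved their median between -0.085 and 0.27. Both calls ended without CD61Low of mouse 2 (adjusted p = 0.339 and 0.137), that of the first list without both libraries of mouse 2 (0.0790), and both when members shared with another list were removed (adjusted p = 0.970 and 0.785). Without the block, the mixed form of fry passed for these lists (adjusted p = 0.00685) and for no other. Neutrophil markers were lower in CD61High beside both lists, with median differences of -2.03, -0.88 and -2.64 in mice 1, 2 and 3.

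Immediate-early genes, which respond within minutes to signals and stress, fell as a list in CD61High by a median of 0.81 (adjusted p = 1.5e-10; adjusted p = 0.514 with an estimated correlation). The median difference was -0.96, -0.74 and -1.08 in mice 1, 2 and 3. Of 26 members, Fos fell over all genes with the block, 18 fell with the block and 3 without it when adjusted over the list alone, and 19 were lower in all 3 mice. The median was -0.34 without CD61Low of mouse 2 and -1.36 without CD61High of mouse 2. Egr1 had 464 ± 114 CPM (SD, n = 3) in CD61High and 1273 ± 391 in CD61Low, and Socs3 36.3 ± 8.41 and 91.2 ± 29.0. The NF-kB and inflammatory cytokine list fell by a median of 0.62 (adjusted p = 7.4e-05; adjusted p = 0.514 with an estimated correlation), with 15 members lower and 1 higher with the block over the list alone, and its median was -0.29 without CD61Low of mouse 2 and -0.33 without CD61High of mouse 3. Its member Ccl4, a chemokine, had 4.76 ± 1.01 and 15.1 ± 2.82 CPM, and Tnfrsf1b 164 ± 6.998 and 261 ± 35.2. Interferon response genes fell by a median of 0.33 (adjusted p = 0.0121; adjusted p = 0.514 with an estimated correlation). No member was called with or without the block. Tap1 went the other way, at 0.42 (SE 0.14), and Mx2 was at 0.257 and 1.34 CPM. That call ended without CD61Low of mouse 2 (adjusted p = 0.235), without CD61High of mouse 3 (0.0910) and, with the block, without mouse 2 (0.0785). Monocyte markers were also lower in CD61High in each mouse, with median differences of -1.89, -0.88 and -0.86.

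Quiescence-associated genes fell by a median of 0.44 (adjusted p = 0.00111; adjusted p = 0.514 with an estimated correlation), alike in the 3 mice at -0.45, -0.46 and -0.54. Cyp26b1 fell over all genes with the block, and 12 of 26 members fell when adjusted over the list alone. Meg3, a long noncoding RNA of the Dlk1 locus, had 0.0987 ± 0.0683 CPM (SD, n = 3) in CD61High and 1.25 ± 0.417 in CD61Low, and Foxo1 44.2 ± 10.2 and 69.6 ± 13.5. Genes higher in aged HSCs fell by a median of 0.21 (adjusted p = 0.0135; adjusted p = 0.729 with an estimated correlation). Of these, Alcam, Sult1a1 and Procr fell with the block, and 8 of 39 fell with it when adjusted over the list alone. The median differences were -0.27, 0.08 and -0.50. Gda, guanine deaminase, had 101 ± 36.4 CPM in CD61High and 267 ± 19.8 in CD61Low. HSC identity and self-renewal genes missed the threshold without the block (median -0.30, adjusted p = 0.0518) and passed with it (adjusted p = 0.0118; adjusted p = 0.645 with an estimated correlation). Sult1a1 and Procr of this list fell with the block, and 9 members were lower and 1 higher over the list alone. Ifitm1 had 307 ± 98.8 and 643 ± 281 CPM. TGF-beta and BMP signalling genes fell by a median of 0.26 (adjusted p = 0.0143; adjusted p = 0.729 with an estimated correlation), and 3 of 29 fell with the block over the list alone. Bmpr1a had 22.5 ± 1.29 and 43.7 ± 8.95 CPM, and Pmepa1 1.15 ± 0.226 and 2.71 ± 0.569. Lysosome and autophagy genes fell by a median of 0.31 (adjusted p = 0.00369; adjusted p = 0.729 with an estimated correlation), and 2 of 36 fell with the block over the list alone. Ctsc had 292 ± 28.2 and 455 ± 31.6 CPM, and Ctsl, with 26.9% of its exon sequence in overlapping genes, 88.2 ± 14.2 and 138 ± 30.8. Leaving out CD61Low of mouse 1, CD61High of mouse 2 or CD61Low of mouse 3 ended the calls of the aged HSC list (adjusted p = 0.278, 0.815 and 0.946) and of the TGF-beta list (0.0553, 0.0950 and 0.346). Without CD61Low of mouse 2 the medians of these lists were -0.55 and -0.42. Leaving out CD61Low of mouse 2 or CD61High of mouse 3 ended that of the lysosome list (0.339 and 0.120), while the HSC identity list passed without CD61High of mouse 1 (0.00510), CD61Low of mouse 2 (2.5e-07) or CD61High of mouse 3 (0.0120). With the neutrophil score and the block together, the medians of the HSC identity, aged HSC and TGF-beta lists turned to 0.30, 0.25 and 0.23. Beside these lists, the neutrophil share was higher in CD61Low in each mouse, as 2.31% against 0.596% in mouse 1.

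**Figure D3:**
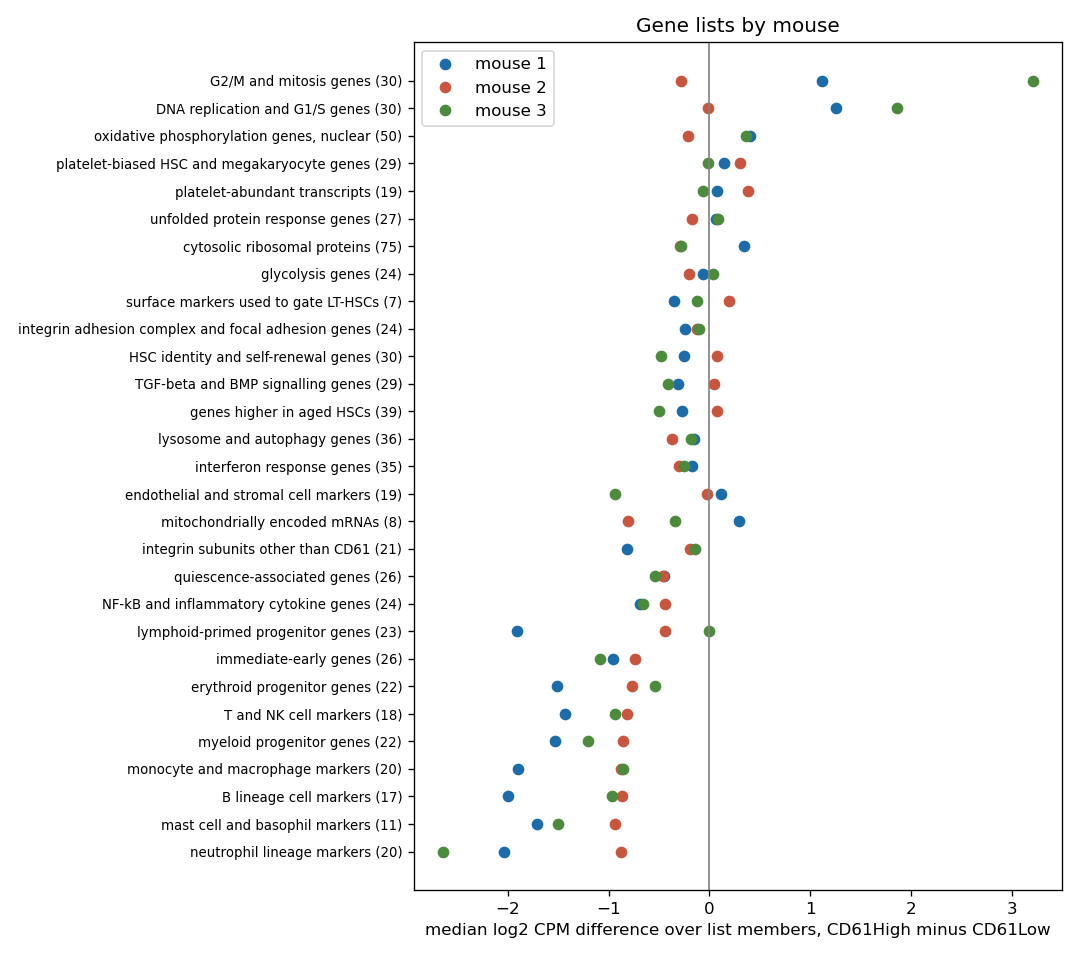
Median log2 CPM difference, CD61High minus CD61Low, over the tested members of each of the 29 lists, with 1 point per mouse and the number of members in brackets. Immediate-early genes lie at -0.96, -0.74 and -1.08, while DNA replication genes lie at 1.25 and 1.86 in mice 1 and 3 and at -0.01 in mouse 2.

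The neutrophil, monocyte, B lineage, T and NK cell and myeloid progenitor lists had medians below 0. Neutrophil markers had a median of -0.96 (adjusted p = 0.00955), monocyte and macrophage markers -0.97 (0.00525), B lineage markers -1.06 (0.00556), T and NK cell markers -0.93 (0.00955) and myeloid progenitor genes -0.96 (0.00832), and each had adjusted p = 0.729 with an estimated correlation. With the block these medians were -1.86, -1.18, -1.36, -1.32 and -1.33 in the same order, with adjusted p of 3.0e-27, 3.0e-12, 3.7e-15, 2.0e-05 and 2.8e-16, each with adjusted p = 0.339 with an estimated correlation. Pglyrp1 of the neutrophil list fell with the block, as did Ms4a3 of the myeloid progenitor list, which was chosen after its values were seen. Adjusted over the list alone with the block, 18 of 20 neutrophil, 15 of 20 monocyte, 16 of 17 B lineage, 8 of 18 T and NK and 17 of 22 myeloid progenitor genes fell. H2-Aa and Cd74, antigen presentation genes of the B lineage list, had blocked log2 fold changes of -1.08 (SE 0.16) and -1.52 (SE 0.22), and Retnlg of the neutrophil list -2.11 (SE 0.35). The calls of all 5 lists ended without CD61Low of mouse 2, with adjusted p of 0.914 (neutrophil, B lineage and myeloid progenitor), 0.964 (T and NK) and 0.988 (monocyte), and without CD61High of mouse 3, with 0.917, 0.743, 0.879, 0.879 and 0.435 in the same order. Without CD61High of mouse 2 the medians of the 5 lists lay between -4.42 and -2.67. Without CD61High of mouse 1 the neutrophil (0.0921), B lineage (0.0762), myeloid progenitor (0.112) and monocyte (0.180) calls ended. These leave-out fits had no block and kept 1 gate of the mouse concerned, so differences between mice entered the gate difference. Within each mouse the medians of all 5 lists were below 0, as -2.03, -0.88 and -2.64 for neutrophil markers in mice 1, 2 and 3.

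Erythroid progenitor genes (median -0.82, adjusted p = 0.244), lymphoid-primed progenitor genes (-0.80, 0.254) and mast cell and basophil markers (-1.01, 0.0803) passed over all 6 libraries only with the block (adjusted p = 1.9e-09, 8.1e-04 and 2.5e-05, and with an estimated correlation adjusted p = 0.339, 0.554 and 0.339), with 14 of 22, 9 of 23 and 6 of 11 members lower with the block over the list alone. Of the lymphoid-primed genes, Cd34 rose with the block, and 2 were higher with it when adjusted over the list alone. Without the block these 3 lists passed camera without CD61High of mouse 2 (adjusted p = 3.5e-05, 0.00351 and 0.00223) or CD61Low of mouse 3 (4.1e-04, 0.00891 and 0.00107). Without CD61Low of mouse 2 the erythroid list passed camera in the other direction (median 1.39, adjusted p = 0.0292). That fit kept mouse 2 in CD61High only, while the erythroid median within mice 1, 2 and 3 was -1.51, -0.77 and -0.54. Hbb-bs, a beta globin, had 2962 ± 4419 CPM (SD, n = 3) in CD61High and 7523 ± 11288 in CD61Low, and Ltb, a lymphotoxin subunit, 92.0 ± 18.6 and 183 ± 28.5.

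The other 7 lists did not pass camera with or without the block. Integrin subunits other than CD61 had a median of -0.53 (adjusted p = 0.682), with Itga2b higher with the block and the other 20 tested members not called over the 6 libraries. Integrin adhesion complex and focal adhesion genes had a median of -0.22 (adjusted p = 0.335). Fermt3, an integrin activator, had 850 ± 14.6 CPM (SD, n = 3) in CD61High and 595 ± 16.8 in CD61Low. In edgeR without the block its log2 fold change was 0.51 (SE 0.13) at an adjusted p of 0.656. Tns1, a focal adhesion protein, had -1.22 (SE 0.37) and 0.676 in that fit. Neither gene was called with the block. The fit without the block recovered 0% of the simulated 4-fold changes, so its adjusted p says little here. Glycolysis genes (median -0.13, adjusted p = 0.555), unfolded protein response genes (-0.15, 0.335), cytosolic ribosomal proteins (-0.05, 0.272), mitochondrially encoded mRNAs (-0.35, 0.110) and endothelial and stromal cell markers (-0.45, 0.246) did not pass either. Of their members with the smallest p, Pfkp (0.51, SE 0.18), Calr (0.32, SE 0.14), Rpl27 (0.42, SE 0.18), mt-Nd6 (-0.61, SE 0.37) and Col1a1 (-2.55, SE 1.67) had adjusted p from 0.715 to 0.851 in edgeR without the block. No member of these lists was called with the block over the 6 libraries. Leaving out CD61High or CD61Low of mouse 1 brought the ribosomal (8.0e-05 and 0.00642) and mitochondrial (0.0221 and 0.0385) lists past the test. The mitochondrial list also passed without CD61Low of mouse 3 (0.00743), and the endothelial list without CD61Low of mouse 1 (0.0229) or CD61High of mouse 2 (0.0109).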

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

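The fits with a neutrophil marker score, the blocked fits with other scalings, fry with the block and the list tests without mouse 2 were chosen after seeing the data. Of 33 other settings of the gene count, 23 gave 0 genes as the edgeR fit without a block did (1023 genes at an unadjusted p under 0.05), limma voom without a block among them, and 10 gave more. The mouse as a block gave 40 genes in edgeR, 489 in limma voom and 1524 in DESeq2, while DESeq2 without it gave 133. The block with relative log expression factors gave 88 genes, with upper-quartile factors 8, and with a neutrophil score 70, of which 6 were among the 40 and in the same direction. Leaving out libraries or mice moved the count between 0 and 742. Without CD61Low of mouse 2, 35 of the 40 genes kept their sign, and with the neutrophil score without a block 38 did. The 17 list calls became 0 with an estimated correlation, 0 with it and the mouse block, 0 with fry without or with the block, 2 with its mixed form without the block and 19 with it, and 11 with the neutrophil score. Leaving out libraries or mouse 2 gave 10 to 20 lists. In the sample structure, the first principal component held 68.2% of the variance over all genes, 84.8% over the 1000 most variable genes, and 90.7% without Itgb3 and the genes called with the mouse block. No named gene passed the fit without a block that other settings are set against, so keeping the side of the threshold meant staying uncalled. Over the 84 named genes, 1807 values from other settings kept their direction and side of the threshold, 256 passed in the same direction and 31 changed direction. Over the 29 lists, read by camera direction, these numbers were 367, 40 and 41, and 131 values no longer passed. The mouse block by itself turned the sign of no named gene and the camera direction of no list, while the median of platelet-biased HSC and megakaryocyte genes went from -0.035 to 0.041. The cause was not tested unless a setting uses fewer libraries or genes.

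The neutrophil score was lower in CD61High in each mouse, so a fit with it and the mouse block extrapolates to an equal score that no mouse had. With the neutrophil score and the mouse block together, which leave 1 residual degree of freedom, the log2 fold change of Itgb3 became 0.28, Ttk -0.60, Bub1b -1.31, Ndufa9 -0.20, Flt3 -0.40 and Emcn 0.90. In this fit the median of HSC identity and self-renewal genes became 0.30, genes higher in aged HSCs 0.25, DNA replication and G1/S genes -0.75, G2/M and mitosis genes -1.85 and lymphoid-primed progenitor genes 0.060. That of integrin subunits other than CD61 became 0.068, TGF-beta and BMP signalling genes 0.23, nuclear oxidative phosphorylation genes -0.28, cytosolic ribosomal proteins -0.032, surface markers used to gate LT-HSCs -0.40 and endothelial and stromal cell markers 0.44. With the score alone, Hbb-bt was at 0.072, Hbb-bs at 0.060, and the log2 fold change of Slamf1 was -0.088 and that of Kit -0.18. The median log2 fold change of integrin subunits other than CD61 was then -0.039. This and the medians of erythroid progenitor genes (0.20), glycolysis genes (0.038), neutrophil lineage markers (0.057) and mast cell and basophil markers (-0.026) had a camera direction opposite to that without the score, and for these the cause was not tested. The log2 fold change of Kit was -0.0033 with relative log expression factors, -0.017 with upper-quartile factors and -0.0056 with a mean of at least 5 CPM. Without members of other lists, the median of platelet-biased HSC and megakaryocyte genes was -0.11 and that of platelet-abundant transcripts -0.16.

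Leaving out single libraries or mice turned the sign of 10 named genes, given as lowest to highest value. The log2 fold change of Iglc2 ranged from -4.92 to 0.74, Tspo2 from -4.48 to 1.49, Hbb-bt from -4.19 to 1.48, Hbb-bs from -4.19 to 1.55 and Cd48 from -4.02 to 0.51. Slamf1 ranged from -0.20 to 0.53, Kit from -0.37 to 0.44, Retnlg from -4.34 to 0.85, Il1rl1 from -4.11 to 0.33 and Col1a1 from -3.59 to 1.10. For lists, leaving out single libraries or mouse 2 turned the camera direction of 12. Of these, HSC identity and self-renewal genes kept a median below 0, from -0.56 to -0.082. The median of myeloid progenitor genes ranged from -3.39 to 0.86, erythroid progenitor genes from -3.74 to 1.39 and integrin subunits other than CD61 from -0.61 to 0.21. Integrin adhesion complex and focal adhesion genes ranged from -0.39 to 0.026, glycolysis genes from -0.19 to 0.087, cytosolic ribosomal proteins from -0.24 to 0.054 and mitochondrially encoded mRNAs from -0.58 to 0.087. Unfolded protein response genes ranged from -0.20 to 0.17, surface markers used to gate LT-HSCs from -0.21 to 0.23, neutrophil lineage markers from -4.42 to 1.43 and monocyte and macrophage markers from -3.41 to 0.84. The medians of 11 other lists crossed 0 with the camera direction kept. Without CD61Low of mouse 2, B lineage cell markers (-3.65 to 0.34), T and NK cell markers (-2.67 to 0.34), mast cell and basophil markers (-3.05 to 1.03), lymphoid-primed progenitor genes (-2.91 to 0.33), endothelial and stromal cell markers (-0.91 to 0.50) and lysosome and autophagy genes (-0.38 to 0.0099) did so. Without CD61Low of mouse 3, G2/M and mitosis genes (-0.050 to 2.26), nuclear oxidative phosphorylation genes (-0.014 to 0.46) and genes higher in aged HSCs (-0.55 to 0.016) did. Platelet-abundant transcripts (-0.085 to 0.27) crossed in 4 of 8 such fits and platelet-biased HSC and megakaryocyte genes (-0.023 to 0.14) in 6. These fits hold fewer libraries. Those without a single library have no block and keep 1 gate of its mouse, so differences between mice enter the gate difference.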

Other observations

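The correlation between mice, the spread over neutrophil markers and the count over the 25 lower genes were set out before their results were seen, and all other tests in this part, the splits included, were chosen after. Several genes outside the naming rule, chosen after their values were seen, also fell in CD61High with the mouse as a block. Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, had 130 ± 37.5 CPM (SD, n = 3) in CD61High and 300.0 ± 102 in CD61Low, and Cd82, a tetraspanin, 122 ± 74.7 and 247 ± 149. Cd200r1, an inhibitory receptor, had 22.3 ± 4.45 and 49.8 ± 8.41 CPM. Wnt4, a secreted signalling protein, had 3, 2 and 1 counts in CD61High of mice 1, 2 and 3, and 114, 52 and 150 counts in CD61Low.

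Transcripts of mature marrow cells differed between libraries. The share of neutrophil markers varied 283-fold while total counts varied 1.24-fold. A share is already divided by the library's total, so setting the 2 ratios side by side is no test of depth. All 5 mature-cell lists had medians over 1 log2 unit higher in mouse 2 than in mouse 3 in both gates. These mice were compared after their marker shares had been seen, so the comparison restates the pattern. It cannot tell whether mature marrow cells or their RNA were carried over in different amounts. The lineage and CD48 gates were set to remove such cells. S100a8 reached 23548 CPM of total counts in CD61Low of mouse 2, and 4 of the 20 neutrophil markers stand in another list. Whether the neutrophil RNA had 1 source stays open, as the SD over markers of the CD61High minus CD61Low difference was highest at 0.675 in mouse 3, where 13 of the 20 markers had the 50 counts required in both libraries. Of the 25 genes lower in CD61High with the mouse as a block, 7 were higher in mouse 2 than in mouse 3 in both gates, too few for carryover to account for the set. Of these 7, 2 (Pglyrp1 and Ms4a3) belong to a mature-cell or myeloid progenitor list. Iglc2 and Igkv6-15, immunoglobulin genes, and Tspo2, an erythroid gene, are also among the 7 but stand in no such list. List membership thus undercounts transcripts of mature lineages, and carryover stays open for the 7.

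DNA replication genes were higher in CD61High in mice 1 and 3 and not in mouse 2. Counts on the listed mature-cell markers would dilute CD61Low by log2 0.0034 in mouse 3, where the median of the replication list was 1.86. These markers are only a part of the RNA of mature cells, so the value sets no upper limit on dilution. Cycling myeloid progenitors carried over in CD61High would raise the myeloid progenitor list, whose highest median over these mice was -1.20. Of its 22 members, 9 stand in another list, and neutrophil and monocyte markers were lower in CD61High in each mouse. These could hold the median below 0 in either case, so it cannot exclude such progenitors. The G2/M list was 4.20 log2 units higher in CD61Low of mouse 2 than of mouse 3, against 0.67 in CD61High. The gap between these values largely restates the list's differences within mice 2 and 3, -0.28 and 3.20. It therefore cannot tell whether dividing marrow precursors hide a difference in mouse 2. A difference in cycling between the gates stays open as untested.

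Itga2b mRNA rose in CD61High with the mouse as a block while Itgb3 mRNA was lower in 2 of 3 mice. A swap of labels in the pair of 1 mouse would turn its differences against those of the others, and the lowest correlation across genes between mice was 0.264, with genes not being independent replicates; a swap in all 3 pairs could not be tested. Platelets attached to CD61High cells stay open: with the block Tubb1, at 3.09 CPM in CD61High and 4.42 in CD61Low, was at -0.58 (SE 0.37) and Tmsb4x, with a high baseline, at -0.53 (SE 0.22), beside 1.21 (SE 0.27) for Ppbp and 1.47 (SE 0.37) for Pf4, all at adjusted p of 0.0847 or above. Whether surface CD61 follows the level of its partner subunit stays open too, since the blocked value of Itga2b, 2.42, is the observation itself and surface protein was not measured beyond the sort.

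The 6 libraries make 10 splits into 3 against 3, too few for a share under 0.05. Without a block, the real split gave 0 genes in edgeR (1023 at an unadjusted p under 0.05; 133 by DESeq2 and 0 by limma voom) and the highest other 1. No split can give fewer than 0, so this count says nothing. The real split gave 17 lists and the highest other 18, and 3 splits gave as many. With the mouse as a block, 4 splits part all 3 pairs, again too few. There the real split gave 40 genes and the highest other 0, and 21 lists against 17, so that 1 split, the real one, gave as many of each.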
